A study of Mus musculus with 8 samples.

How the data were processed

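RNA from whole hippocampus of adult C57BL/6 mice aged 3 to 6 months was measured on Agilent 1-colour arrays with 43020 non-control spots each. Control mice carried 2 floxed copies of Ctcf and no Cre recombinase (WT), and conditional knockout mice (CKO) carried the same floxed alleles with Camk2a-Cre, which deletes Ctcf in excitatory forebrain neurons. Per the labels, each sample was a pool of 3 mice, there were 3 pools of each genotype, and pool 1 of each genotype was hybridised on 2 arrays, giving 8 arrays on 2 slides of 4. Slide 1 held the first arrays of pool 1 and the arrays of pool 2. Slide 2 held the second arrays of pool 1 and the arrays of pool 3. The mice had gone through behavioural tests before tissue collection, per the labels' protocols. Pools with the same number had the same makeup in both genotypes: pool 1 held 2 females and 1 male aged 19 to 23 weeks, pool 2 held 3 females aged 18 to 19 weeks, and pool 3 held 3 males aged 15 to 17 weeks. Labelled sample was hybridised in the Cy5 (red) channel alone, per the labels.

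The scanner files hold the spot intensity as given by Agilent Feature Extraction 11.5, per the submitters' processing notes (11.5.1.1 per the file headers). Per the file headers, the processed signal is an intensity that was background-subtracted and detrended within each array, with surrogates for low values, and not normalized between arrays. The other deposited columns used were flags (well above background, saturated, spot outlier). The series value table deposited by the authors holds linear intensities that rank within each array as the background-subtracted signal does (Spearman's rho across spots of 1 in all 8 arrays); its array medians ran from 651.7 to 944.0, it is empty at the 4342 to 5314 spots per array whose background-subtracted signal is not positive, and its step between arrays is not given in the sources used here. It was used as an alternative. The build in the file headers (mm9) differs from that of the gene table used for names (GRCm38.p6), so no coordinates are given.

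The median processed signal ran from 271.9 to 600.5 and the 75th percentile from 2112 to 5104; 59.2% to 66.0% of spots were well above background and 0 were saturated. The second arrays of both first pools were the dimmest, with 75th percentiles of 2112 (WT) and 2883 (CKO) against 3949 or more in the others. The second array of WT pool 1 correlated with its mate at r = 0.952 across probes, against 0.989 for both arrays of CKO pool 1. In a check with sex-linked genes, 0 of the 6 pools departed from the sex makeup in the labels.

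Values were log2 of the processed signal minus the 75th percentile of non-control spots of the array. Outlier-flagged spots were left out, spots of one probe were averaged, and both arrays of a pool were averaged, so that n is 3 pools per genotype. Of 39429 probes, 27508 were named through a RefSeq accession, 3544 by symbol, 404 by synonym, and 7973 kept the name in the file. The 23648 probes well above background on every array of at least 1 genotype were kept, and each of the 18336 genes was read by its brightest probe. Of the named genes, 23 had more than 1 measured probe, and in 9 of them the probes differed in sign, among them Bcl11b, Sox4 and Tcte1 of those given in the text. Some genes that the rule below takes are not reported here. Genotypes were compared with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over genes and an adjusted p threshold of 0.05. A probe not well above background on any array of a genotype is given as "at least N-fold": the brighter genotype's mean over the mean of, per array of the dimmer one, the higher of the lowest well-above-background signal and the probe's own. An exact test of 3 pools against 3 cannot give a p under 0.1.

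The comparison and 29 gene lists were fixed before the data were examined, with the series title known, which names microglia and inflammation. Of these, 28 were tested with limma's camera (preset correlation 0.01, adjusted over 28 lists), and the sex-linked list served only as the check above. The rule for named genes, fixed likewise, took Ctcf, the 10 genes of largest log2 difference in each direction past the threshold with pools that did not overlap (filled up with the genes of smallest unadjusted p, given as values that did not pass), and up to 4 members of each list by unadjusted p, leaving out clone and accession names; others named in the text were chosen after their values were seen.

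Same-numbered pools deviated together from their genotype means, with correlations across genes of 0.54, 0.31 and 0.15 for pools 1, 2 and 3. All were over 0.1. The highest between differently numbered pools was 0.126. The labels give same-numbered pools the same sex and age makeup and name no other link, and where the shared deviation comes from was not tested. With the first array of each pool alone the correlations were 0.08, 0.06 and 0.14, against a highest of 0.0816 between differently numbered pools, so without the second arrays those of pools 1 and 2 were not over 0.1. For pools 1 and 2 the shared deviation thus rests on the second arrays of pool 1, and a pairing of the samples is not shown. The fit without the block was the main one, and the fit with pool number as a block stands beside it where it changes the call of a list or gene in the text.

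The code was tested on 10 simulated sets of 18336 genes with the spread of these pools and 200 changed genes: for the CKO against WT comparison it called 81.8% of genes changed by 2 on the log2 scale, 39.5% of those changed by 1, 0.448% of those changed by 0.5 and 0.0155% of unchanged genes, with 0 calls in the wrong direction, and it called a list shifted by -0.5 in all 10 sets and 0 other lists. Noise was drawn independently for each gene, whereas the estimated correlation among members of a list reached 0.936 in these pools. The simulated sets therefore could not show how often camera calls lists whose members move together. Alternatives were normexp background, quantile and median scaling, the authors' table, both other probe filters, the pool number or slide as a block, each slide alone, first arrays alone, eBayes without trend or robust, array weights, the mean of a gene's probes, each pool left out, other thresholds, and 3 other set tests. Added after seeing the data were the fits without the second WT pool 1 array, quantile scaling with the block or with first arrays, the choroid plexus level as a covariate, the fits without probes that hold a run of GAA repeats, and the estimated correlation with the block. Figures were drawn with matplotlib 3.10.9.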

Results

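Gene expression in whole hippocampus was compared between mice lacking Ctcf in Camk2a-Cre-expressing neurons (CKO) and controls with the same floxed alleles and no Cre (WT), with 3 pools of 3 mice per genotype on 8 arrays. CTCF is a zinc-finger protein that binds insulator sites and, with cohesin, anchors chromatin loops. The comparison asks which transcripts differ in hippocampal tissue when excitatory neurons lose it. As only CKO mice carried Cre, effects of Cre or its transgene are not separated from those of Ctcf loss. Between 59.2% and 66.0% of spots on each array were well above background.

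The deleted gene came first. Ctcf signal, read by 1 probe, was 1.00 ± 0.15 (SD, n = 3) in WT pools and 0.13 ± 0.07 in CKO pools on the log2 scale relative to the array 75th percentile, a difference of -0.87 (SE 0.13). All 3 CKO pools lay below all 3 WT pools, and the WT level was 1.82-fold the CKO level. In the limma test over 18336 genes the adjusted p was 0.144, and it was 0.0284 with the pool number as a block. Whether the probe lies within the floxed exons is not given in the sources used here. Without the second array of WT pool 1, where Ctcf stood at 0.57 against 1.04 to 1.12 on the other WT arrays, the difference was -0.95 (adjusted p = 0.00463). The 15 measured genes of the CTCF and cohesin machinery list, which holds partners such as Stag1 (+0.27, SE 0.17), Nipbl (+0.37, SE 0.25) and Wapl (+0.17, SE 0.15; with 1 pool left out 0.10 to 0.35, 0.20 to 0.63 and 0.11 to 0.23), had a median difference of 0.02 and 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.510).

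Of 18336 genes, 6 were higher and 0 lower in CKO pools at an adjusted p under 0.05 by limma, with 538 higher and 468 lower at an unadjusted p under 0.05, where 917 are due by chance. Mnd1, a partner of meiotic recombination, rose most, 9.91-fold, from -3.16 ± 0.46 (SD, n = 3) to 0.15 ± 0.22 (adjusted p = 0.00776); it was well above background on 3 of 4 WT arrays, and its other probe gave +3.49. Robo3, a guidance receptor of commissural axons, rose 4.74-fold (log2 difference 2.25, SE 0.18, adjusted p = 0.00776). Asl, the urea cycle enzyme argininosuccinate lyase, rose 2.57-fold (1.36, SE 0.12, adjusted p = 0.0170). Nmbr, the neuromedin B receptor, rose 3.21-fold (1.68, SE 0.18), and Cyp11a1, the cholesterol side-chain cleavage enzyme that starts steroid synthesis, rose 3.56-fold (1.83, SE 0.20), both at adjusted p = 0.0382. Krt78, a keratin, was not well above background on any WT array and was at least 1.57-fold higher in CKO pools (adjusted p = 0.0492). In each of these 6 genes all CKO pools lay above all WT pools. Such separation in either direction was seen in 11.3% of the 18336 genes, where 10% is due by chance, so alone it says little. The next genes by unadjusted p did not pass. Among them the relaxin receptor gene Rxfp1 had a difference of +1.75 (SE 0.21, adjusted p = 0.0502), Tigd3 of +1.31, Parp3 of +1.24 and Fchsd1 of +1.24. These passed with the pool number as a block, at adjusted p of 0.00551, 0.0154, 0.0231 and 0.0154.

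On the lower side, where no gene passed, the smallest unadjusted p belonged to Ajm1, an apical junction gene, at -0.98 (SE 0.12, adjusted p = 0.0502). Wfs1, an endoplasmic reticulum protein used as a marker of CA1 pyramidal cells, followed at -0.91 (SE 0.12, adjusted p = 0.117). Icam4 differed by -1.33, Psg16 by -1.28, Tcte1 by -0.93, Dennd6b by -0.81, Fbxo27 by -1.14, Pdzd9 by -1.29 and Otop2 by -1.41, with adjusted p from 0.123 to 0.148. With the block these passed, at adjusted p of 0.0219, 0.0274, 0.0274, 0.0389, 0.00928, 0.0241 and 0.0284 in the same order, as did Ajm1 and Wfs1, both at 0.0154; without GAA-repeat probes Dennd6b did not (0.0513). Otop2 was well above background on 2 of 4 CKO arrays, and a second Tcte1 probe gave +0.28.

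With the pool number as a block, 106 genes passed, 73 higher and 33 lower, and these held all 6 genes above. Of the 73 higher genes, 23 were read by probes with a run of at least 18 bases of GAA repeats; without such probes the blocked fit gave 32 genes higher and 24 lower. The call of 6 genes went to 0 without WT pool 3 or without CKO pool 3, to 18 without WT pool 1 and to 2 without CKO pool 1. It went to 101 without the second WT pool 1 array and to 0 within slide 2. Of those 101 genes 56 were among the 106 of the blocked fit, as were 59 of the 112 that passed with first arrays alone.

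**Figure D1:**
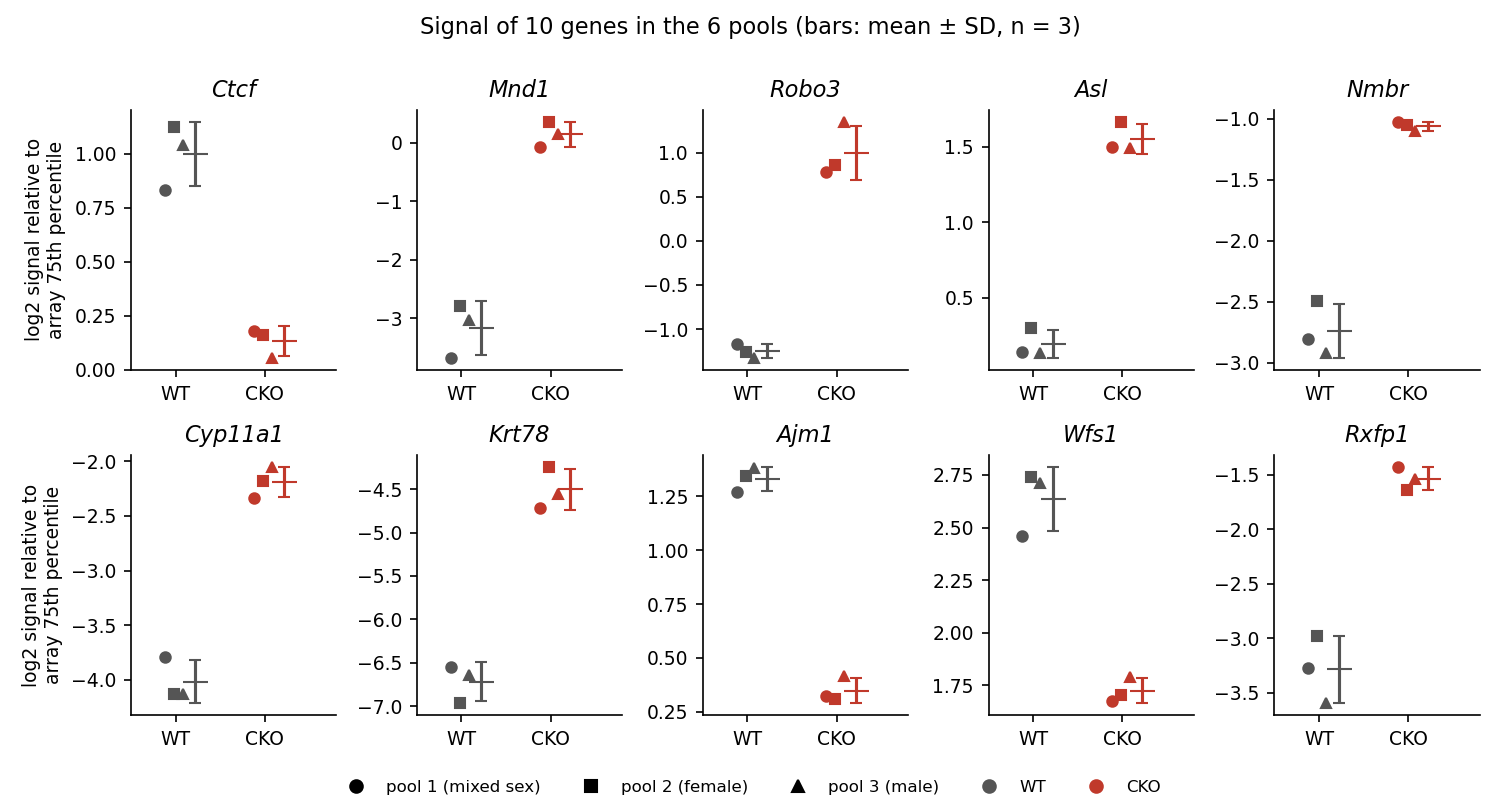
Log2 signal of 10 genes relative to the array 75th percentile in each of 3 WT and 3 CKO pools. Symbols are pools, bars are mean ± SD (n = 3); CKO pools of Ctcf, Ajm1 and Wfs1 lie below all WT pools and those of the other 7 genes above.

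Of the 28 lists tested, 10 were higher and 2 lower in CKO pools by camera with a preset correlation, and 0 kept the call with an estimated correlation. In none of them did a member pass over all genes in the fit without the block. Camera also called up to 14 lists in other splits of the 6 pools into groups of 3, so each of the 12 lists is given with the values or range of its CKO pools relative to the WT mean.

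The clustered protocadherins, neuronal adhesion proteins whose isoform promoters bind CTCF, fell. Of 23 measured members 20 were lower, with a median difference of -0.61 (camera adjusted p = 1.08e-15; adjusted p = 0.0669 with an estimated correlation; fry adjusted p = 0.0346). None passed over all genes and 15 passed, all lower, when adjusted over the list alone. Pcdhb17 differed by -0.84 (SE 0.18), Pcdhb18 by -0.74 (SE 0.17), Pcdhb13 by -0.88 (SE 0.20) and Pcdhb3 by -0.86 (SE 0.20). The mean of the list lay below the WT mean by -0.45, -0.51 and -0.64 in CKO pools 1, 2 and 3, and WT pools lay between -0.07 and 0.06. The median was -0.61 within slide 1 and -0.51 within slide 2.

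The reactive astrocyte list, genes that astrocytes raise in injury and inflammation, rose. Of 25 measured members 22 were higher, with a median of 0.48 (camera adjusted p = 7.59e-11; adjusted p = 0.0669 with an estimated correlation; fry adjusted p = 0.0393), and 8 passed adjusted over the list alone. Osmr, the oncostatin M receptor, differed by +0.78 (SE 0.15), the protease inhibitor Timp1 by +1.85 (SE 0.39), the endotoxin co-receptor Cd14 by +1.07 (SE 0.25) and the cytokine signalling inhibitor Socs3 by +1.11 (SE 0.26). With the block, Timp1, Cd14, Socs3, Gfap and Serpina3n passed over all genes, at adjusted p of 0.0241, 0.0200, 0.0286, 0.0433 and 0.00526; in the blocked fit with quantile scaling Socs3 did not pass (0.0535), nor did Gfap without GAA-repeat probes (0.0539). Without the block the adjusted p of Gfap and Serpina3n were 0.493 and 0.576. In the list mean all CKO pools (0.36 to 0.60 above the WT mean) lay above all WT pools (-0.10 to 0.11). The astrocyte identity list did not differ by camera (median -0.0026, adjusted p = 0.940); its members S100b and Slc7a10 stood at -0.22 (SE 0.14) and +0.22 (SE 0.15), or from -0.27 to -0.12 and from 0.13 to 0.36 with 1 pool left out.

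The reactive microglia list, genes of phagocytic and inflamed microglia, rose by camera, with 20 of 26 members higher and a median of 0.29 (adjusted p = 0.000136; adjusted p = 0.468 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The beta-glucan receptor gene Clec7a differed by +1.87 (SE 0.55), the chemokine gene Ccl6 by +1.08 (SE 0.33), Cd52 by +1.38 (SE 0.47) and Lilrb4a, well above background on 2 of 4 WT arrays, by +1.25 (SE 0.44). Without CKO pool 2 these were 1.16, 0.67, 0.80 and 0.79. The list mean was 0.41 above the WT mean in CKO pool 1, 0.70 in pool 2 and 0.01 in pool 3. With the choroid plexus level as a covariate the call was lost (median 0.19, adjusted p = 0.137). The list passed in 27 of 31 alternatives, all of them with the preset correlation, and not by fry (adjusted p = 0.470). The homeostatic microglia list did not pass (15 of 25 higher, median 0.09, adjusted p = 0.0519), and it passed with the block (adjusted p = 0.0173; adjusted p = 0.674 with the block and an estimated correlation); without CKO pool 1 or 3 the adjusted p was 0.0418 or 6.55e-05. It passed in 11 of 31 alternatives, among them quantile scaling (0.0381), median scaling (0.0219), no filter on dim probes (0.00521), the slide as a block (0.0481), slide 1 alone (0.00821) and no GAA-repeat probes (0.0460). Gpr84 stood at +1.20 (SE 0.33) and Sparc at +0.36 (SE 0.19; 0.17 without WT pool 3). Border macrophage and leukocyte genes did not pass (median 0.01, adjusted p = 0.560).

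A further 4 immune lists were called by camera. Cytokines, chemokines and NF-kB targets rose (15 of 22 higher, median 0.37, adjusted p = 0.00113; adjusted p = 0.429 with an estimated correlation; 2 members past the threshold adjusted over the list alone). Ccl2, a monocyte chemoattractant, differed by +2.47 (SE 0.46) and was well above background on 1 of 4 WT arrays, and the receptor gene Tlr2 differed by +1.53 (SE 0.27, 3 of 4 WT arrays); their blocked adjusted p were 0.00318 and 0.0241. The list mean in CKO pools 1, 2 and 3 was 0.53, 0.42 and 0.27, and WT pools lay between -0.13 and 0.22. With probes well above background on all arrays this list was not called (median 0.15, adjusted p = 0.132). Complement genes rose (12 of 16 higher, median 0.19, adjusted p = 0.000960, or 0.429 with an estimated correlation), with C4b at +0.70 (SE 0.22) and Cd55 at +0.54 (SE 0.16). Without CKO pool 2 the camera adjusted p of complement was 0.0591, at a median of 0.16. The CKO pools stood at 0.33, 0.49 and -0.03, and WT pools between -0.10 and 0.18. Interferon-stimulated genes (28 of 32 higher, median 0.14, adjusted p = 0.0113; adjusted p = 0.676 with an estimated correlation) and antigen presentation genes (18 of 22 higher, median 0.22, adjusted p = 0.0170; adjusted p = 0.669 with an estimated correlation) rose by camera, with Ifi27l2a at +0.92 (SE 0.27) and H2-D1 at +0.42 (SE 0.21; 0.21 without CKO pool 2 and 0.65 without CKO pool 3). The CKO pools stood at 0.25, 0.52 and -0.25 for interferon-stimulated genes and at 0.30, 0.59 and -0.31 for antigen presentation, so that in both CKO pool 3 lay below all WT pools (lowest -0.06). Both lost the call without CKO pool 2 (adjusted p = 0.944), where the medians fell to -0.0086 and 0.017. They also lost it without WT pool 1 (0.112 and 0.128), where the medians were 0.21 and 0.19. Antigen presentation lost it also without WT pool 3 (0.0716, median 0.19) or CKO pool 1 (0.0606, median 0.15). Within slide 2 the adjusted p were 0.927 and 0.917, and those of complement and of cytokines 0.505 and 0.0692. With the choroid plexus level as a covariate interferon genes (median 0.16, adjusted p = 0.438) and antigen presentation genes (median 0.11, adjusted p = 0.460) were not called, and they passed in 20 and 19 of 31 alternatives, against 26 for complement and 26 for cytokines.

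**Figure D2:**
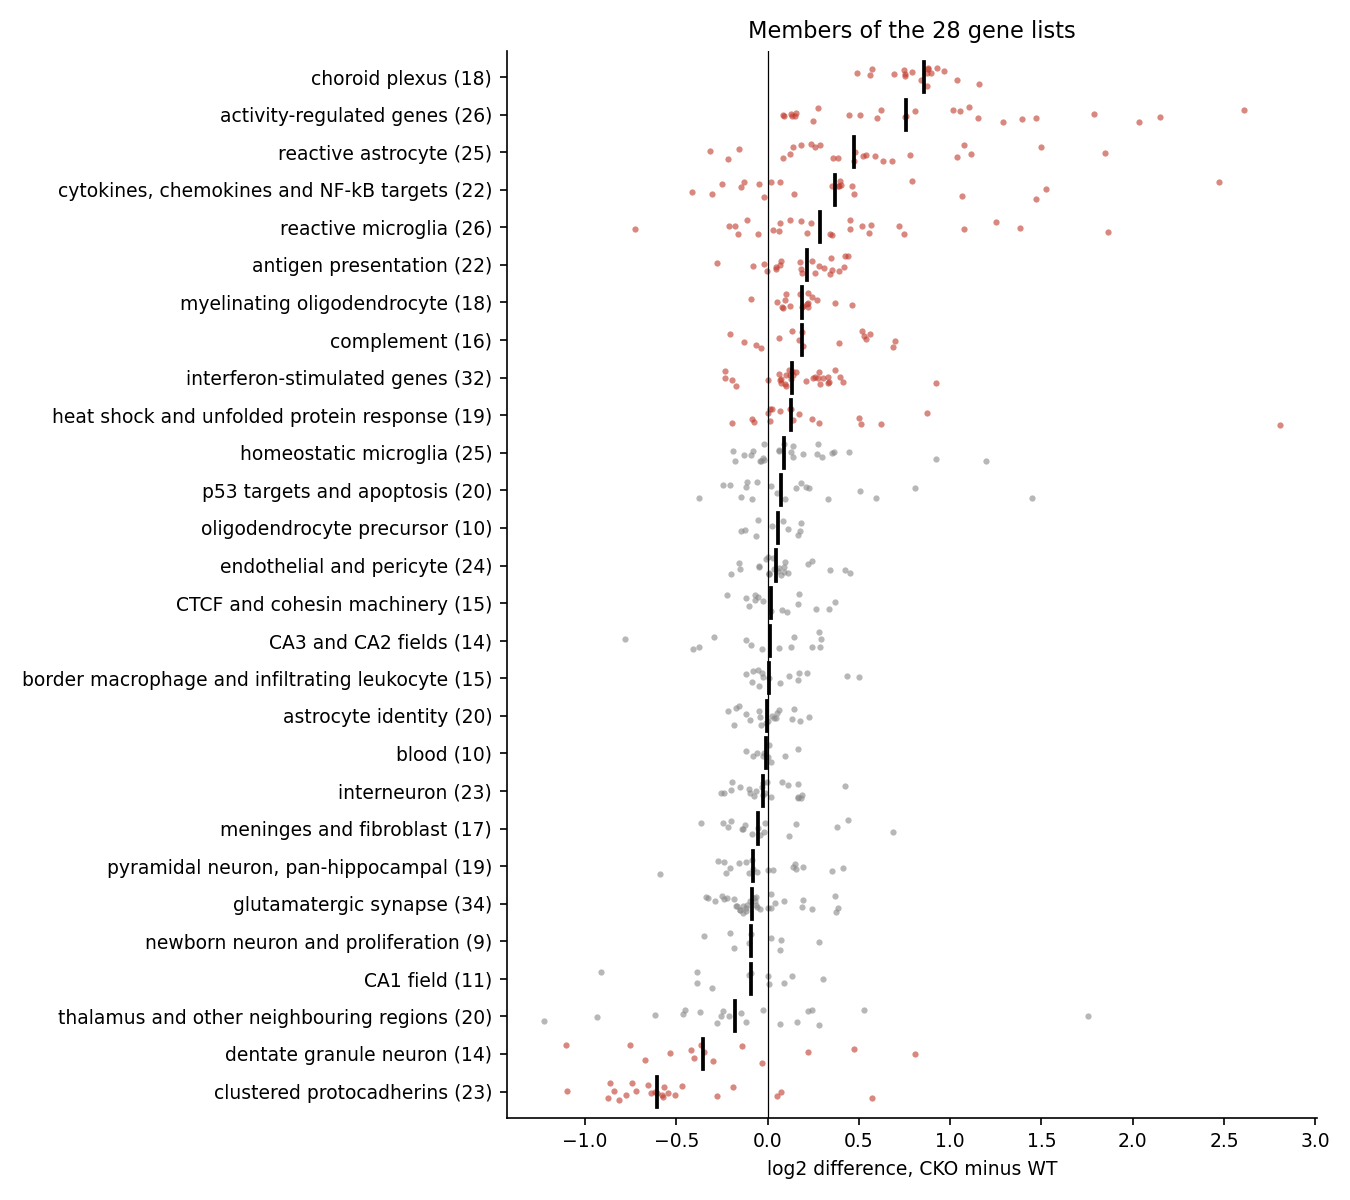
Log2 difference (CKO minus WT) of each measured member of the 28 lists, with the number of members in brackets. Points are genes, black lines are medians and red points mark the 12 lists past the camera threshold with a preset correlation; the protocadherin median is -0.61 and the reactive astrocyte median 0.48.

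Activity-regulated genes, transcribed within minutes to hours of neuronal firing, rose by camera: 26 of 26 members were higher, with a median of 0.76 (adjusted p = 3.52e-10; adjusted p = 0.429 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The list mean was 1.60 above the WT mean in CKO pool 1 and 1.20 in pool 3, and -0.17 in pool 2, where the WT pools ran from -0.12 to 0.21. Inhba differed by +2.61 (SE 0.84), Gadd45b by +1.29 (SE 0.42), Nptx2 by +1.47 (SE 0.50) and Pim1 by +1.39 (SE 0.57), and without CKO pool 1 these were 1.70, 0.82, 0.90 and 0.68; with the block Inhba and Gadd45b passed (adjusted p = 0.0429 and 0.0442), and neither did without GAA-repeat probes (0.0539 and 0.0541) or with quantile scaling (both 0.0785) in the blocked fit. Heat shock and unfolded protein response genes rose by camera (16 of 19 higher, median 0.13, adjusted p = 0.00264; adjusted p = 0.429 with an estimated correlation), led by the stress factor gene Atf3 at +2.81 (SE 0.54, well above background on 2 of 4 WT arrays, blocked adjusted p = 0.0037), with Ddit3 at +0.50 (SE 0.16); without WT pool 1 the adjusted p was 0.0906, without WT pool 2 it was 0.0507 and with the choroid plexus level as a covariate it was 0.0992 (medians 0.22, 0.046 and 0.23), and the list passed in 23 of 31 alternatives. The CKO pools stood at 0.51, 0.12 and 0.34, and WT pools between -0.08 and 0.08. Of its members 1, Atf3, passed adjusted over the list alone. Of p53 targets, Cdkn1a stood at +1.45 (SE 0.34, blocked adjusted p = 0.0274, or 0.0530 with quantile scaling) and Ccng1 at +0.59 (SE 0.12), and the list of 20 did not pass (median 0.07, adjusted p = 0.147; passed in 2 of 31 alternatives), with 2 members past the threshold adjusted over the list alone.

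Dentate granule neuron genes fell by camera, with 11 of 14 members lower and a median of -0.36 (adjusted p = 0.000146; adjusted p = 0.111 with an estimated correlation), and 3 members passed adjusted over the list alone. C1ql2 differed by -1.10 (SE 0.30), the desmosome gene Dsp by -0.75 (SE 0.20) and Stxbp6 by -0.42 (SE 0.12); with the block C1ql2 passed over all genes (adjusted p = 0.0433), and it did not without GAA-repeat probes (0.0539) or with quantile scaling (0.0666) in the blocked fit. All CKO pools (-0.36 to -0.11) lay below all WT pools (-0.07 to 0.05), and the adjusted p was 0.331 within slide 2; the list passed in 27 of 31 alternatives. The CA1 list did not pass (7 of 11 lower, median -0.09, adjusted p = 0.0635) and passed with the block (adjusted p = 0.0451; adjusted p = 0.643 with the block and an estimated correlation). The pan-hippocampal pyramidal list (median -0.08, adjusted p = 0.303), CA3 and CA2 (0.01, adjusted p = 0.718), interneuron (-0.03, adjusted p = 0.958), newborn neuron (-0.09, adjusted p = 0.304) and glutamatergic synapse lists (-0.09, adjusted p = 0.147) did not pass. Without WT pool 3 the CA1, pyramidal and synapse lists passed (adjusted p = 0.0423, 0.0344 and 0.0403), and CA1 also without CKO pool 3 (0.00605). Within slide 1 the CA1, pyramidal, CA3 and CA2, and synapse lists passed as lower (adjusted p = 0.00360, 0.00536, 0.0350 and 0.00596). CA1 passed in 9 of 31 alternatives, also with quantile scaling (0.0381) and the slide as a block (0.0481). Bcl11b stood at -0.59 (SE 0.19), Map3k15 at -0.78 (SE 0.20), Npy at +0.42 (SE 0.13), Sox4 at -0.35 (SE 0.15) and Vamp2 at +0.37 (SE 0.15).

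Choroid plexus genes were higher in 18 of 18 members (median 0.86, camera adjusted p = 2.31e-09; adjusted p = 0.429 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The list mean of WT pool 1 was -1.23 relative to the WT mean, and the other 5 pools lay between 0.48 and 1.01; without WT pool 1 the adjusted p was 0.0514 and with array weights it was 0.0958. Enpp2 differed by +0.69 (SE 0.21) and the clotting factor gene F5 by +1.04 (SE 0.41), or 0.46 and 0.50 without WT pool 1. Myelinating oligodendrocyte genes were higher in 17 of 18 members (median 0.19, adjusted p = 0.000960; adjusted p = 0.429 with an estimated correlation), with Mobp at +0.37 (SE 0.13) and Cnp at +0.27 (SE 0.12). The CKO pools stood at 0.11, 0.31 and 0.11 and the WT pools at -0.16, -0.03 and 0.19; without WT pool 1 the adjusted p was 0.266, without CKO pool 2 it was 0.0831, within slide 2 it was 0.445 and with the choroid plexus level as a covariate it was 0.699 (median 0.084). Oligodendrocyte precursor (median 0.06, adjusted p = 0.718), endothelial and pericyte (0.04, 0.304), meningeal (-0.05, 0.990), blood (-0.01, 0.990) and thalamic and other neighbouring region lists (-0.18, 0.304) did not pass; without CKO pool 3 the endothelial list did and the meningeal list did in the other direction, as higher (median 0.075), both at an adjusted p of 0.0411.

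**Figure D3:**
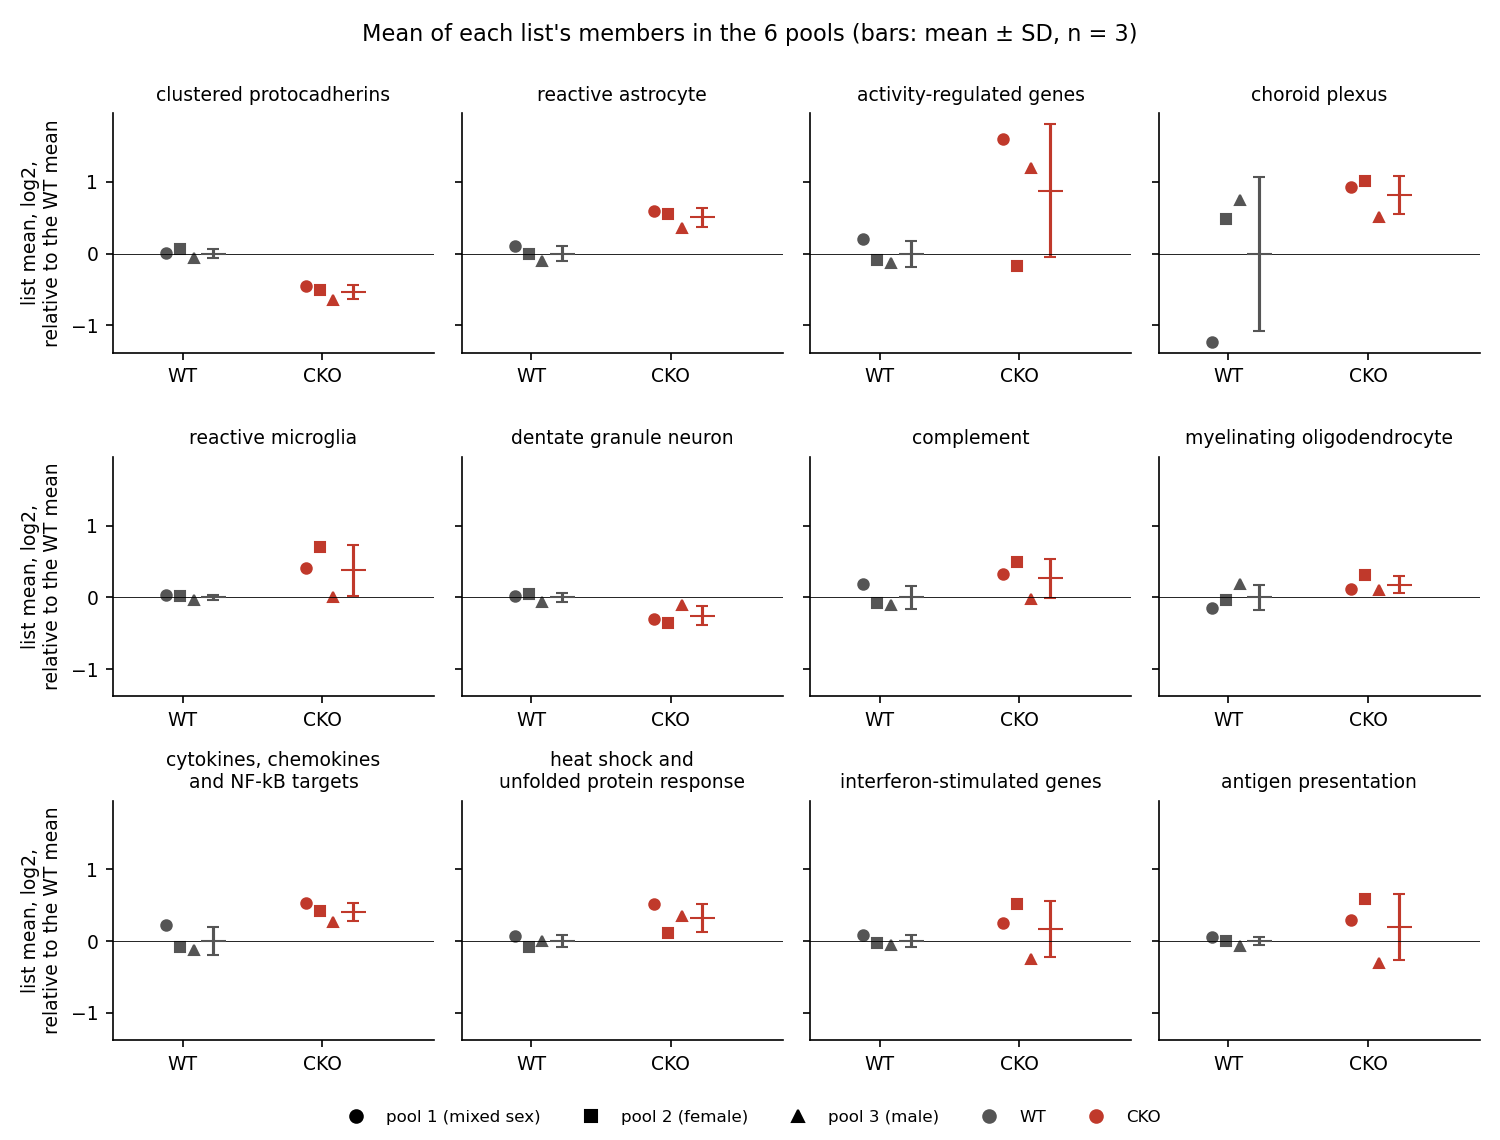
Mean of each list's members in the 6 pools for the 12 lists past the camera threshold, in log2 units relative to the WT mean. Symbols are pools and bars are mean ± SD (n = 3); the protocadherin, reactive astrocyte, dentate granule, cytokine and heat shock lists part all CKO from all WT pools, and WT pool 1 stands at -1.23 for choroid plexus.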

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

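In 5 of the 12 lists past the camera threshold the log2 difference of the all-female pair of pools (pool 2) and of the all-male pair (pool 3) had opposite signs, with 1 pair of each kind. The signs were also opposite in 9 of the 16 lists not past it. These were picked out after the values were seen, and the difference was not tested. Activity-regulated genes stood at -0.080 in the female pair and 1.32 in the male pair. Choroid plexus genes stood at 0.53 and -0.23, and myelinating oligodendrocyte genes at 0.35 and -0.079. Interferon-stimulated genes stood at 0.55 and -0.19, and antigen presentation genes at 0.58 and -0.25. The pools also differ in age, per the labels, and in slide (pool 2 on slide 1, pool 3 on slide 2). Sex, age and slide are therefore not separated here.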

How the results depend on the processing

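The counts of genes, of lists and the Ctcf difference rest on 3 pools per genotype, and signal over background limits Krt78 to a lower bound. The fit of 6 genes gave 3 with the authors' value table, 106 with the pool number as a block (56 without GAA-repeat probes, 75 with quantile scaling), 14 within slide 1, 0 within slide 2, 112 with first arrays alone (141 with quantile scaling, of which 41.8% were higher), 604 with array weights, 101 without the second WT pool 1 array, 443 at an unadjusted p under 0.05 and 1.5-fold, and from 0 to 18 with 1 pool left out. Ctcf differed by -0.87 with the block (adjusted p = 0.0284; 0.0357 without GAA-repeat probes, also -0.87), -0.89 with quantile scaling and the block (0.0365), -0.92 with first arrays (0.00743), -0.93 with quantile scaling and first arrays (0.0107), -0.91 with array weights (0.00443), -0.95 without the second WT pool 1 array (0.00463) and from -0.95 to -0.80 with 1 pool left out (0.0307 to 0.682); over all alternatives it ran from -0.98 to -0.74 with adjusted p from 0.00443 to 1.00. The count of 12 lists was 7 within slide 2 and with array weights, 6 with the choroid plexus level as a covariate (which ended the calls of reactive microglia at a median of 0.19, antigen presentation at 0.11, myelin at 0.084 and choroid plexus, and of interferon at 0.16 and heat shock at 0.23, medians above those of 0.14 and 0.13 without it), 2 by fry, 0 with an estimated correlation with or without the block, and from 7 to 16 with 1 pool left out. With 1 pool left out the medians ran from -0.0086 to 0.38 for interferon-stimulated genes, 0.017 to 0.45 for antigen presentation, -0.14 to 0.075 for meninges, 0.23 to 1.23 for choroid plexus, 0.40 to 1.20 for activity-regulated genes, 0.10 to 0.45 for complement, 0.046 to 0.22 for heat shock, 0.15 to 0.44 for reactive microglia, 0.10 to 0.28 for myelin and 0.21 to 0.45 for cytokines; with its own level as a covariate the choroid plexus median was 0.0032, as built in. The block changed the calls of the homeostatic microglia and CA1 lists (adjusted p = 0.0173 and 0.0451), of Ctcf and of the genes given with blocked values, and no other call of a list or of a gene taken by the rule; the cause was not tested. Of 3471 values for named genes 3229 kept call and sign, 40 were weaker, 178 stronger, 24 moved and 0 reversed, and of 868 for lists 709, 67, 28, 60 and 4.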

Other observations

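With the pool number as a block further named genes passed that lie outside the lists. Tnfrsf12a, the TWEAK receptor, was higher by 1.17 (adjusted p = 0.00928) and Plaur, the urokinase receptor, by 1.36 (0.0193), as were Cwh43 (1.93, 0.00526), Serpinf2 (1.51, 0.0236) and the nicotinic receptor subunit gene Chrna1 (1.46, 0.0241). Lower were Ulk3 (-0.99, 0.00916), Rprm (-0.997, 0.0154), the enkephalin precursor gene Penk (-0.83, 0.0216) and the adrenergic receptor gene Adra2c (-0.98, 0.0242). None of these passed without the block, where the adjusted p ran from 0.148 for Chrna1 and Adra2c to 0.807 for Ulk3. The pools of Ulk3 overlapped between genotypes (4.59 ± 0.71 in WT and 3.60 ± 0.54 in CKO, SD, n = 3).

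Of the 58 clustered protocadherins in the list 23 were measured, 17 of them of the beta cluster. All 17 beta members were lower (median -0.64, 14 past the threshold adjusted over the list alone), as were 3 of 3 measured members of the alpha cluster (median -0.28). In the gamma cluster 3 of 3 measured members stood above 0 (median 0.07). They were Pcdhga9 at +0.05 (SE 0.12), Pcdhgb1 at +0.07 (SE 0.25) and Pcdhgc5 at +0.57 (SE 0.30). The smallest unadjusted p of these by limma was 0.0941, so a rise of this cluster is not shown. The largest fall was that of Pcdha9 of the alpha cluster (-1.10, SE 0.37). The clusters were split after the values were seen and the difference was not tested.

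The tests of 1 array, loss of pyramidal or dentate granule neurons, choroid tissue, more microglia and GAA repeats were chosen only after the results were seen; the others were written before. Hypothesis 1 is that 1 array hid part of the gene calls: without the second WT pool 1 array 101 genes passed, against 6. With 10 splits too few for a share under 0.05, the real split gave 6 genes and the highest other 2 (1 of 10 splits with as many), and the real split gave 12 lists and the highest other 14 (3 of 10). With the block, the real split gave 106 genes and the highest other 0 (1 of 4 splits), and the real split gave 14 lists and the highest other 15. Of the 73 genes higher with the block, 31.5% were read by probes with a run of GAA repeats. All 41 such probes tested were higher in CKO pools (median 0.88, pool means 0.01 ± 0.10 in WT and 0.91 ± 0.18 in CKO, n = 3), so that part of the count may be 1 shared signal of the repeat and not separate genes; 10 probes with GGA runs had a median of -0.05.

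Hypothesis 2 is that the protocadherin fall (median -0.61) came from probes shared between members or from loss of neurons. Of the 23 probes 0% shared 20 bases with the probe of another member. The probes were compared only with one another, so binding of a probe to the transcript of another member was not tested and stays open. The pyramidal list had a median of -0.082 (mean -0.037, SE 0.054 over members and 0.078 over pools), which argues against loss of pyramidal cells as the whole cause. The dentate granule list had a median of -0.36 (mean -0.25, SE 0.13 over members and 0.083 over pools), within that error of the bound of -0.30 set for it. The protocadherin mean was -0.53 (SE 0.068 over pools). In CKO pools 1, 2 and 3 the dentate granule list stood at -0.29, -0.36 and -0.11, against -0.45, -0.51 and -0.64 for the protocadherins. This smaller fall in every CKO pool, compared after the values were seen, argues against loss of dentate granule cells as the whole cause. Such loss stays open as part of the cause. The genotype, and whether loss of CTCF at their promoters lowers them, were not tested apart from the comparison itself.

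Hypothesis 3 is that choroid plexus tissue entered some pools. The members' deviations from their genotype means correlated at 0.936 on average and the pools of WT spanned 1.97, a pattern that may come from dissection. No biological explanation was tested for this list.

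Other tests are given as values. Reactive minus homeostatic microglia genes stood at 0.21 (SE 0.10) on average over the 3 pairs of pools (0.33, 0.27 and 0.02), which leaves open whether more microglia could account for the reactive list. Neighbours were read for 43 of the 50 genes higher with the block and not read by GAA-repeat probes, those with a place and a measured neighbour in the gene table. Neighbours with a name of the same family were left out of the means. These were Ucp2 (0.92), C2cd4a (0.88), Ccl12 (0.79), Serpina3i (0.66), Serpinf1 (0.06) and Robo4 (-0.02). The mean difference of the remaining neighbours was 0.12 (one-sided permutation p = 4.0e-04). The median over the 43 genes was 0.046, with 26 above 0. Without neighbours past the threshold themselves it was 0.05 over 42 genes (permutation p = 0.0672), a check chosen after the result was seen. Rxfp1 (1.75) lies between 4930579G24Rik (2.14) and Tmem144 (0.88), and these called genes of 1 place entered the mean of 0.12 as neighbours of one another. Mnd1 (3.31) and Tlr2 (1.53) lie on either side of Tmem131l, which stood at -0.05. Neighbours of 24 of the 33 lower genes had a mean of -0.050 (one-sided permutation p = 0.0589), and the brighter neighbour of a higher gene a mean level of 1.24 (one-sided permutation p = 0.204). Sex, age and the behavioural tests before harvest were not tested as explanations.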
